A study of Triticum aestivum with 10 samples.

How the data were processed

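Total RNA of leaves and of shoots holding the shoot apical meristem was extracted from 2 lines of synthetic hexaploid wheat, made into Cy3-labelled cRNA and hybridised to one-colour Agilent arrays, per the labels' protocols. There was 1 array per sample and there were 2 samples in each of 5 groups: necrotic line leaf at 23 °C, wild-type and necrotic line leaf after 12 weeks at 4 °C, and wild-type and necrotic line shoot after 6 weeks at 4 °C. Groups and replicate numbers were taken from the sample labels. Wild-type leaf at 23 °C was not analysed here.

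The scanner tables deposited by the authors hold spot intensity values on a linear scale, made with Agilent Feature Extraction. The version is 10.5.1.1 per the file headers and 9.5 per the submitters' processing notes, and the difference was left as it stands. Per the file headers, the processed intensity is background-subtracted and detrended within each array, with a surrogate value for dim spots, and it is not scaled between arrays. The series matrix deposited by the authors holds intensity values equal to the processed signal at all 39243 features of the 10 arrays, with a largest relative difference of 0. Its scale is therefore linear and uncentred, with no ratio whose direction would have to be found. The median of its columns was 104.8 and 106.3 for the necrotic leaf at 23 °C, 212.6 and 189.5 for the wild-type leaf at 4 °C, and 196.4 and 186.5 for the necrotic leaf at 4 °C. It was 301.2 and 292.6 for the wild-type shoot and 316.1 and 305.7 for the necrotic shoot.

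From these files, control spots were left out, which kept 37826 probes, each present once. The log2 of the processed signal minus the array's 75th percentile was the level of a probe. Before scaling, that percentile was 789.5 and 807.7 on the arrays at 23 °C and 1539 to 1901 on the others. Spots marked as non-uniform or population outliers (12 to 143 per array) were treated as missing. A probe was tested if it was well above background on both arrays of at least 1 group. The model had 1 mean per group over all 10 arrays, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (files were read with the data.table package, version 1.17.8), with 5 residual and 1.56 prior degrees of freedom. The median residual SD was 0.079 on the log2 scale. P-values were two-sided and adjusted by Benjamini-Hochberg over all probes of a comparison, and a probe was called at an adjusted p under 0.05. Counts of at least 2-fold changes also require a log2 difference of 1. These choices, the 4 comparisons and the alternatives were fixed before the data were examined. The comparisons were necrotic against wild-type leaf at 4 °C, necrotic against wild-type shoot at 4 °C, necrotic leaf at 4 °C against 23 °C, and the difference between the leaf and the shoot line differences. The precision of each value is limited by the number of arrays, 2 per group.

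A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. A count of probes detected in 1 group only requires the probe to be well above background on both arrays of that group and on neither array of the other, with an adjusted p under 0.05.

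No table used here pairs the probes with gene descriptions. None of the 37826 probe names was found in the table of reference genes, which follows the wheat assembly IWGSC CS RefSeq v2.1, so that 0 matched. 41 names have the form of a sequence accession, 238 hold a gi number, and 6 are gene names: Wcor15, cor47, RD29A, RD29B, DREB2A and DREB2B. Of 29 lists of gene groups written before the data were examined, the list of cold-responsive proteins matched 4 probes (Wcor15, cor47, DREB2A and DREB2B), of which 1 was tested, and the other 28 lists matched 0. No list reached the 3 tested probes set as its minimum, and no list was tested. For probes without a description, the rule fixed beforehand names the 2 largest rises and the 2 largest falls of a comparison among those called, at least 2-fold changed and with both arrays of a group beyond both of the other. Because values near background have no order, the ranking was limited to probes well above background on both sides, a restriction added later, and names in the form of an accession were passed over. The probes with a gene name are given whatever their result.

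Per the file headers the arrays fall into 3 slides and scans. Slide 1 held the 2 arrays at 23 °C, slide 2 the 4 shoot arrays and slide 3 the 4 leaf arrays at 4 °C. Each line comparison thus lies within 1 slide, and its difference is a within-slide value. The temperature comparison lies between slides, no fit with slide as a term can be made for it, and slide and temperature cannot be told apart.

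The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the array median, the series value table, no filter on dim probes, probes well above background on all 10 arrays only, a fit on the groups of a comparison only, an intensity trend in eBayes, the replicate number or the slide as a block, and leaving out each array in turn. A mean signal column is not among those used here, so normexp ran on the median signal and median background. The fit was tested on simulated data with the residual spread of each of 33089 probes and 200 changed probes. For the leaf, shoot and temperature comparisons it recovered 42%, 39% and 44% of changes of 0.5 on the log2 scale and 78%, 78% and 80% of changes of 1. The sign was right in 100% of the recovered changes, and 6.25%, 4.88% and 4.62% of the calls were false. The simulated share of changed probes was far below the share called in the data. The adjusted threshold depends on that share, so these percentages do not give the recovery in the data themselves.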

Results

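Transcript levels were measured in 2 lines of synthetic hexaploid wheat, a bread wheat made anew by crossing tetraploid wheat with the goat grass Aegilops tauschii. The wild-type line grew normally, and the necrotic line developed cold-induced hybrid necrosis, a disorder in which tissue of some hybrids dies after growth at low temperature. Total RNA was labelled with Cy3 and hybridised to 10 one-colour Agilent wheat arrays, 2 for each of 5 groups. All plants were grown first at 23 °C for 3 weeks. Leaves of the necrotic line were taken at that point. Leaves of both lines were taken after a further 12 weeks at 4 °C, and shoots holding the shoot apical meristem were taken from both lines after 6 weeks at 4 °C. Leaves of the wild-type line at 23 °C were not analysed here.

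Of the 37826 probes on each array, 28344 and 28779 were well above background in the necrotic leaf at 23 °C. The count was 29203 to 30225 on the 4 leaf arrays at 4 °C and 32068 to 32605 on the 4 shoot arrays, and no spot was saturated. Replicate arrays correlated at r = 0.994 to 0.998 across probes, and the median absolute difference between replicates was 0.062 to 0.098 on the log2 scale. Across probes, which are not independent replicates, the mean levels of the necrotic and wild-type lines correlated at r = 0.975 in leaf and at r = 0.945 in shoot. Leaf and shoot of the wild-type line correlated at r = 0.703, and leaf and shoot of the necrotic line at r = 0.778. All levels below are log2 signals relative to the array's 75th percentile, given as mean ± SD with n = 2. Most probes carry only the name of an expressed-sequence contig or clone, so that gene groups could be described for the few probes with a gene name only. The series description speaks of independent experiments, but the labels do not say whether replicates came from separate plants, and p-values then measure only the spread between these samples.

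The leaf comparison asked which transcripts separate the necrotic from the wild-type line after 12 weeks of cold. In the necrotic leaf 2299 probes were at least 2-fold higher and 1105 at least 2-fold lower than in the wild-type leaf, of 33087 tested with limma. Without a fold requirement 8064 probes were higher and 9715 lower, which was 53.7% of those tested, so most of the differences were smaller than 2-fold. With only the 2 groups of this comparison in the fit, fewer probes were called, 6307 higher and 7435 lower (41.5%). Wcor15, a cold-responsive wheat gene whose product is targeted to the chloroplast, was close to the array's 75th percentile in both lines. Its level was −0.058 ± 0.0011 in the necrotic leaf and −0.74 ± 0.049 in the wild-type leaf, a difference of 0.68 (SE 0.061) or 1.61-fold with an adjusted p of 0.000136. The 2 arrays of the necrotic leaf lay above both arrays of the wild-type leaf for Wcor15. RD29B is known in Arabidopsis as a gene induced by drought and abscisic acid, and the files do not say from which species the sequence of its probe was taken. It was dim in both lines, at −6.78 ± 0.16 in the necrotic leaf and −6.46 ± 0.017 in the wild-type leaf. That difference of −0.32 (SE 0.091) passed the threshold at an adjusted p of 0.024. The call was lost without either wild-type array (adjusted p = 0.066 and 0.0761) or without replicate 1 of the necrotic line (0.113), and also with normexp, with an intensity trend or with only the 2 groups in the fit; over all alternatives its adjusted p ran from 0.00602 to 0.955.

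The probe with the largest rise among those measured in both lines was wheat0130Contig1162, at 1.64 ± 0.0083 in the necrotic leaf against −5.72 ± 0.24 in the wild-type leaf. That is a 165-fold difference (adjusted p = 4.1e-05). MUGEST2003_23lib_Contig3816_293 followed, 146-fold higher in the necrotic leaf (7.19 on the log2 scale, SE 0.17, adjusted p = 4.18e-07). Among probes that were lower in the necrotic leaf, MUGEST2003_23lib_Contig14513_354 stood at −5.87 ± 0.091 against 0.49 ± 0.019, an 82.3-fold difference (adjusted p = 5.29e-08). MUGEST2003_23lib_Contig20768_385 was 62.2-fold lower (adjusted p = 3.02e-07). For each of these 4 probes both arrays of the one line lay beyond both arrays of the other, which the rule that chose them requires. Over the alternatives their folds ran from 52.6 to 185, 37.9 to 177, 23.4 to 86.1 and 22.4 to 65.6, in the order given. In leaf 442 probes were well above background on both necrotic arrays and on neither wild-type array, against 142 probes with the opposite pattern. The 2-fold counts given above were not limited to probes detected in both lines and can include these probes. With normexp background correction the 2-fold counts were 1215 higher and 476 lower and the count of 142 became 67; among probes well above background on all 10 arrays the 2-fold counts were 1384 and 690.

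**Figure D1:**
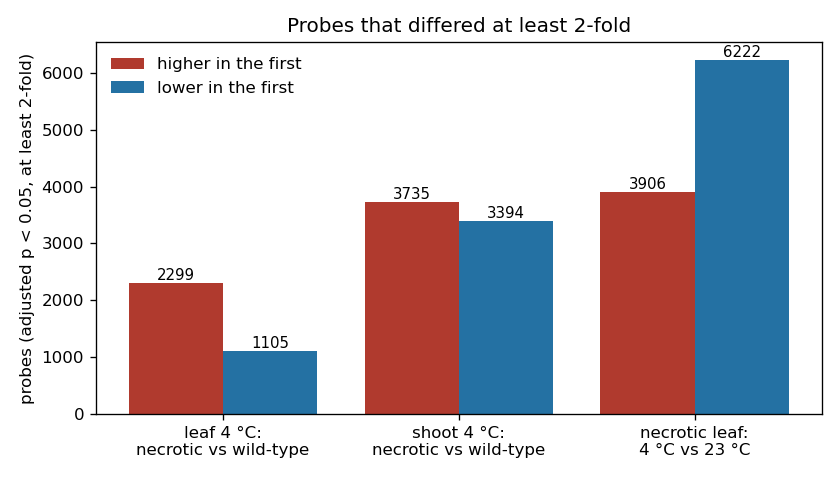
Number of probes with an adjusted p under 0.05 and a difference of at least 2-fold, for necrotic against wild-type leaf at 4 °C, necrotic against wild-type shoot at 4 °C and necrotic leaf at 4 °C against 23 °C; red bars count probes higher in the first-named group and blue bars probes lower in it. The leaf bars stand at 2299 and 1105, the shoot bars at 3735 and 3394 and the temperature bars at 3906 and 6222.

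The same question was asked in shoots with their apical meristem after 6 weeks of cold, where more probes differed. In the necrotic shoot 3735 probes were at least 2-fold higher and 3394 at least 2-fold lower than in the wild-type shoot, of 33089 tested. Without a fold requirement 10710 were higher and 11955 lower, or 68.5% of those tested. With only the 2 shoot groups in the fit these counts were 11393 and 13033 (73.8%). Wcor15 was measured in the wild-type shoot at −6.02 ± 0.047 and was not well above background on either necrotic shoot array. It was at least 5.62-fold lower in the necrotic shoot (adjusted p = 2.45e-08), a bound set against the lowest signal well above background. The direction was opposite to that in leaf, and by the same bound the line difference in leaf minus that in shoot was at least 3.17 on the log2 scale (adjusted p of the fit = 1.23e-07). With normexp, whose offset compresses dim signals, the fitted shoot difference was −0.61 and the fitted difference between the tissues 1.28, both still past the threshold. RD29B stood at −5.34 ± 0.015 in the necrotic shoot and −5.41 ± 0.014 in the wild-type shoot, a difference of 0.066 (SE 0.091) that did not pass the threshold (adjusted p = 0.552).

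The 2 largest measured rises in the necrotic shoot were those of rwhkv10e02_224 and MUGEST2003_23lib_Contig15558_721. The first stood at 1.24 ± 0.032 against −7.57 ± 0.13 in the wild-type shoot, 446-fold higher (adjusted p = 9.86e-09), and the second was 271-fold higher (adjusted p = 3.14e-09). The level of rwhkv10e02_224 was also high in leaf, at 3.59 in the necrotic and 4.39 in the wild-type line at 4 °C, so that the wild-type shoot was the group in which it was low. The largest measured falls were those of wheat0130Contig10922, at −6.40 ± 0.12 against 2.02 ± 0.027 (342-fold, adjusted p = 3.44e-06), and wheat0130Contig13248 (172-fold, adjusted p = 1.47e-07). The signals of wheat0130Contig10922 and wheat0130Contig13248 were at most −8.33 in the 3 leaf groups. In shoots 390 probes were well above background on both necrotic arrays and on neither wild-type array, against 221 with the opposite pattern. Which of the 2-fold counts was larger depends on the setting: they were 2438 higher and 2463 lower with normexp, 3447 and 3859 with scaling to the median, and 2688 and 2061 among probes well above background on all 10 arrays. Over the alternatives the fold ran from 63.7 to 740 for rwhkv10e02_224, 41.7 to 431 for MUGEST2003_23lib_Contig15558_721, 91.0 to 565 for wheat0130Contig10922 and 56.0 to 284 for wheat0130Contig13248.

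**Figure D2:**
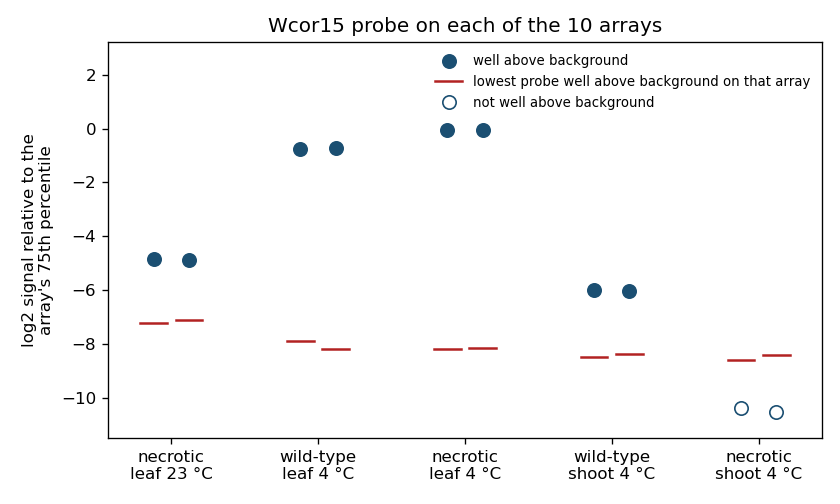
Log2 signal of the Wcor15 probe relative to the array's 75th percentile (vertical axis) on each of the 10 arrays, 2 per group; filled points are well above background, open points are not, and red lines mark the lowest probe well above background on that array. The 4 leaf arrays at 4 °C lie highest, the necrotic leaf at 23 °C and the wild-type shoot lie at −4.87 and −6.02 on average, and both necrotic shoot arrays lie under the red lines.

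Some probes differed between the lines in the same direction in both tissues. Of the 2299 probes at least 2-fold higher in the necrotic leaf, 876 were also at least 2-fold higher in the necrotic shoot, where 259.5 would be expected if the lists were independent. Of the 1105 lower in leaf, 287 were lower in shoot, against 113.4 expected. Opposite changes were fewer but also above that expectation, with 331 probes higher in the necrotic leaf and lower in the necrotic shoot against 235.8 expected, and 150 the other way round against 124.7. The expectation was passed in the same and in opposite directions, so it is too low a reference. The overlaps in the same direction lay further above it. Across probes, which are not independent, the leaf and shoot differences correlated at r = 0.199. With normexp the shared counts were 454 and 88, and among probes well above background on all 10 arrays they were 520 and 156.

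**Figure D3:**
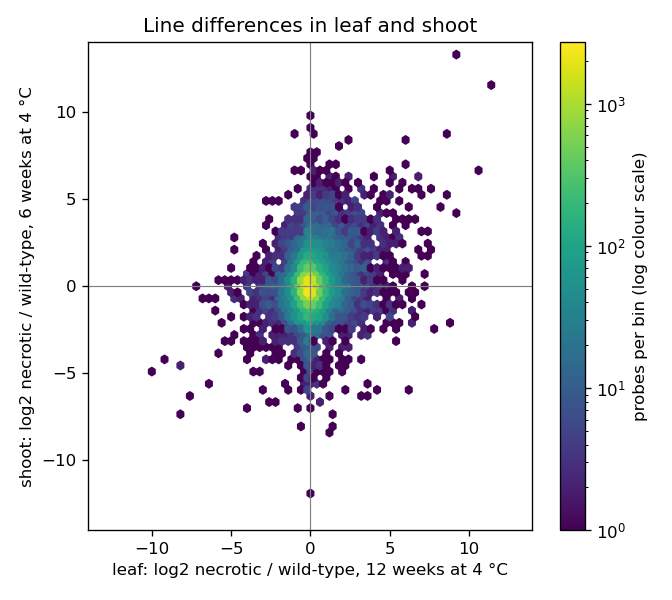
Log2 difference between the necrotic and the wild-type line for each probe in leaf (horizontal axis, 12 weeks at 4 °C) and in shoot (vertical axis, 6 weeks at 4 °C); colour gives the number of probes per bin on a log scale, and fitted values of probes near background in 1 line are included. Most probes lie near 0 on both axes, and the cloud is only weakly tilted (r = 0.199 across probes).

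The difference itself was then tested, as the line difference in leaf minus that in shoot. At least 2-fold, 4456 probes had a higher value in leaf and 4240 a lower one, of 33087 tested, and 10613 and 10823 passed without a fold requirement. Among probes well above background in both lines of both tissues, whsh_allContig905 had the largest positive value, 9.98 (SE 0.075, adjusted p = 2.84e-08). It stood at 2.62 in the necrotic and −0.93 in the wild-type leaf, and at −7.81 in the necrotic and −1.38 in the wild-type shoot. The largest negative value among such probes was that of rwhkv10e02_224, at −9.60 (SE 0.11, adjusted p = 4.48e-08). Tissue and weeks of cold changed together between these arrays, so that the contrast cannot assign the difference to either. Which of the 2-fold counts was larger depends on the setting, with 2945 higher and 3301 lower among probes well above background on all 10 arrays, 3404 and 2644 with normexp and 4262 and 4336 with quantile normalization.

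The temperature comparison was made in the necrotic leaf only and asked what changed between 23 °C and 12 weeks at 4 °C. After the cold 3906 probes were at least 2-fold higher and 6222 at least 2-fold lower, of 33038 tested, and 10188 and 15280 passed without a fold requirement. With normexp the 2-fold counts were 2027 higher and 5165 lower. Among the 26795 probes well above background on all 10 arrays they were 2726 and 4546, and without the filter on dim probes 3915 and 8104. Undetected probes read higher at 23 °C: cor47, RD29A, DREB2A and DREB2B stood at −9.33, −8.99, −9.16 and −9.29 there. In the necrotic leaf at 4 °C they stood at −10.11, −10.34, −10.11 and −10.23. A dim probe can thus count as lower at 4 °C without a change in its transcript. Wcor15 rose from −4.87 ± 0.013 to −0.058 ± 0.0011, a 28.0-fold rise (log2 difference 4.81, SE 0.061, adjusted p = 8.91e-09), with both cold arrays above both arrays at 23 °C; over the alternatives the fold ran from 10.98 to 30.5. RD29B fell from −6.30 ± 0.15 to −6.78 ± 0.16, a log2 difference of −0.48 (SE 0.091, adjusted p = 0.00253). The largest measured rises were those of MUGEST2003_23lib_Contig4076_p_195, from −6.88 ± 0.0073 to 3.81 ± 0.037 (1654-fold, adjusted p = 6.57e-10), and MUGEST2003_23lib_Contig23735_p_373 (972-fold, adjusted p = 1.41e-09). Both were also high in the wild-type leaf at 4 °C, at 2.60 and 5.04. The largest measured falls were those of wheat0130Contig12265, from 2.36 ± 0.055 to −6.33 ± 0.20 (412-fold, adjusted p = 4.73e-09), and wheat0130Contig1176 (345-fold, adjusted p = 2.76e-08). In the wild-type leaf at 4 °C these stood at −6.35 and −4.90. Over the alternatives the folds of the 4 probes ran from 199.6 to 1800.3, 486 to 1059, 104.8 to 454 and 61.8 to 397, in the order given. There were 970 probes well above background on both cold arrays and on neither array at 23 °C, against 247 with the opposite pattern. The lowest level well above background was higher at 23 °C (−7.17 against −8.16 on average), which favours the first count; 794 of the 970 lay above the level for 23 °C.

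The balance of higher and lower calls in the temperature comparison depends on the scaling, besides the effect of dim probes given above. The median log2 difference of all tested probes was −0.21 after scaling to the 75th percentile, −0.083 after quantile normalization, −0.084 after scaling to the median and −0.50 with normexp. After scaling to the 75th percentile 10188 probes were higher and 15280 lower at 4 °C, with normexp 7703 and 21474, with quantile normalization 11164 and 13392 and with scaling to the median 11651 and 13454. Of those at least 2-fold different, 38.6% were higher after scaling to the 75th percentile, 28.2% with normexp, 47.9% with quantile normalization and 47.5% with scaling to the median. Relative to the median probe, the change of RD29B was −0.27 after scaling to the 75th percentile and −0.18 to −0.39 over all 4 settings, while those of Wcor15 and of the 4 probes named by size were far larger than any of these shifts. The 2 arrays at 23 °C were on a slide and in a scan of their own, so that temperature, 12 weeks of plant age, slide and scan cannot be told apart.

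The differences of the cold necrotic leaf from the wild-type leaf and from 23 °C were then compared. Of the 2299 probes at least 2-fold higher than in the wild-type leaf, 1056 (45.9%) were also at least 2-fold higher than at 23 °C, where 271.8 would be expected of independent lists. Of the 1105 lower probes 506 (45.8%) were also lower than at 23 °C, against 208.1 expected. With normexp these shared counts were 496 and 188, and among probes well above background on all 10 arrays 583 and 330. Both comparisons use the same 2 necrotic leaf arrays at 4 °C, which links them by chance alone. In 20 simulations of residual noise without any effect the correlation of the 2 differences was 0.502 and their covariance 0.0249. The observed values were 0.328 and 0.380. No probe was shared at 2-fold or more in the simulations, an outcome fixed beforehand by noise that small. The covariance above the simulated one was 0.355, which shows only that the differences exceed noise. With 1 of these arrays used for the line comparison and the other for the temperature comparison, 1008 and 1002 probes were higher in both (269.0 and 266.7 expected) and 471 and 527 lower in both (205.6 and 237.8 expected), for the 2 ways of assigning them. The covariance was then 0.343 and 0.348. This split, added after the overlap was seen, removes only what differs between the 2 arrays. The level of the cold necrotic leaf still enters both differences, so real but unrelated differences would share probes too. The counts expected of independent lists are therefore too low a reference. The overlap cannot tell a common response from this shared term.

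Of the 6 probes with a gene name, cor47, RD29A, DREB2A and DREB2B were not well above background on any of the 10 arrays and were not tested. In Arabidopsis cor47 and RD29A are known as cold-responsive genes, and DREB2A and DREB2B as transcription factors of the dehydration response.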

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

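The tests of Wcor15 below were chosen only after the result was seen. Each result here stands out because the difference between the lines was not the same in leaf and shoot, by a test of that difference in limma. At least 2-fold, it was higher in leaf for 4456 probes and lower in leaf for 4240. The 2 largest positive values measured in all 4 groups were 9.98 for whsh_allContig905 (adjusted p = 2.84e-08) and 9.25 for whsh_allContig946 (adjusted p = 2.5e-07). The level of whsh_allContig946 was 2.08 in the necrotic and −1.69 in the wild-type leaf, and −7.02 in the necrotic and −1.55 in the wild-type shoot. The 2 largest negative values were −9.60 for rwhkv10e02_224 (adjusted p = 4.48e-08) and −6.89 for wheat0130Contig4923 (adjusted p = 4.48e-08). Over the alternatives these 4 values ran from 7.24 to 10.6, 7.09 to 9.83, −10.4 to −6.83 and −6.94 to −5.07. The level of wheat0130Contig4923 was −5.52 in the necrotic and −0.74 in the wild-type leaf, and −2.01 in the necrotic and −4.12 in the wild-type shoot.

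RD29B differed between the tissues by −0.38 (adjusted p = 0.036), and this call was lost under 10 of 20 alternatives, with adjusted p from 0.0126 to 0.684. Leaving out any 1 of the 8 arrays of both lines at 4 °C other than replicate 2 of the necrotic leaf ended it (adjusted p = 0.0662 to 0.0908).

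Wcor15 had a fitted difference between the tissues of 5.11 (adjusted p = 1.23e-07; 1.28 with normexp), which rests on signals near background in the necrotic shoot and is no bound; the bound is at least 3.17, the probe being 1.61-fold higher in the necrotic leaf and at least 5.62-fold lower in the necrotic shoot. A sequence difference under the probe that acts alike in both tissues, as the only difference between the lines, would dim it in the necrotic line in leaf too. The leaf difference was 0.68 in favour of the necrotic line, which argues against that case only. A sequence difference in a gene copy used mainly in shoot, or 1 outweighed in leaf by a higher transcript level, is not covered. Leaf RNA in the wild-type shoot samples stays open. Of the 1655 probes most abundant in the wild-type leaf, 5.80% (96 probes) lay more than 2-fold below the share Wcor15 has in the wild-type shoot, 2.59% of its leaf level, but leaves after 6 weeks of cold, whose profile this needs, were not analysed here. The difference between the lines in the shoot itself and the weeks of cold, which changed with tissue, stay open and untested, and no shoot at 23 °C was analysed here.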

How the results depend on the processing

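No count or single probe changed direction past its threshold under the alternatives, but the median change of the leaf-rich probes in the shoot turned from 0.89 to −0.53 with classes from the necrotic line. Of the counts of called probes, 147 values under other settings and all 160 with an array left out stayed within 1.5 times the main count, and 17 did not. 8 of these 17 follow from adding the 2-fold requirement, which by construction keeps fewer probes: 2299 and 1105 (higher and lower in the necrotic leaf), 3735 and 3394 (shoot), 3906 and 6222 (4 °C against 23 °C) and 4456 and 4240 (leaf minus shoot). Normexp with its offset of 50 lowered 2-fold counts to 1215 and 476 in leaf, 2438 higher in shoot, 2027 higher at 4 °C and 2644 lower for leaf minus shoot; the cause was not tested, though an offset by construction shrinks the changes of dim probes. Keeping only probes well above background on all 10 arrays, which tests fewer probes, gave 1384 and 690 in leaf, 2061 lower in shoot and 2945 higher for leaf minus shoot. With each array left out, where the lone array of its group is assumed to vary like the other groups, the 2-fold counts ran from 2249 to 2595 and 1084 to 1245 in leaf, 3601 to 3750 and 3170 to 3420 in shoot, and 3840 to 3918 and 6111 to 6304 for temperature. Of the values of single probes, overlaps and classes, 303 planned or added and 340 leave-one-out values kept their side or size, 20 moved, 1 was reversed and 16 lost their call; those 16 were all of RD29B. Same-numbered samples did not deviate together (r = −0.0091 to 0.056 over 10 pairs of groups), so the numbers are not taken as pairs; with the replicate block the counts were 8000 and 9712 in leaf, 10666 and 11887 in shoot, 10138 and 15250 for temperature and 10579 and 10778 for leaf minus shoot. The series value table and, for the line comparisons, the slide block gave the main counts by construction. The table equals the processed signal, and a slide term takes up nothing within a line comparison that lies on 1 slide. Neither is a separate check, although both are counted among the values above that stayed the same. The slide block for temperature and the planned gene list tests were not run, for lack of a slide with both temperatures and of lists with 3 tested probes. Signal over background limits the 23 °C arrays most, where the fewest probes (28344 and 28779) were well above background.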

Other observations

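The classes of probes by tissue, from either line, the tests on them by leaf share and by equal abundance, the count over the 39 probes above the level at 23 °C, and the comparisons by probe name were chosen only after the data were seen; the other tests below, and the bound for classes from the necrotic line, were fixed before their results. Probes were first classed by the wild-type line alone. 1032 shoot-rich probes were at least 32-fold higher in the wild-type shoot than in the wild-type leaf and above the array's 75th percentile there, and 495 leaf-rich probes met the same rule for leaf. Weeks of cold, slide and scan changed with tissue, so the classes cannot be assigned to tissue alone. Of the shoot-rich probes 47.8% were at least 2-fold lower in the necrotic leaf at 4 °C than at 23 °C and 15.2% higher. Of the probes in neither class these shares were 17.9% and 11.4%. The shoot-rich probes were lower in the necrotic than in the wild-type shoot by a median of −1.54 on the log2 scale (2.90-fold; quartiles −1.91 and −0.63), and 687 of them were called at least 2-fold lower and 59 higher. Over the 4 pairs of single arrays the median ran from −1.52 to −1.56. With classes from 1 wild-type shoot array and the contrast from the other it was −1.54, which covers measurement noise only, since those 2 arrays differed by a median of 0.069. The leaf-rich probes were higher in the necrotic shoot by a median of 0.89 (quartiles −0.11 and 2.52), with 238 called at least 2-fold higher and 39 lower; with normexp this median was 0.46. The rise of the leaf-rich probes rests on the line behind the class, since it was −0.53 over 416 probes classed from the necrotic line and 0.13 over the 249 classed so in both lines. The other 31562 probes had a median of −0.029. In leaf the line difference of the shoot-rich probes had a median of 0.11 and that of the leaf-rich probes −0.24.

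If leaf RNA had replaced shoot RNA in the necrotic samples, the fall of the shoot-rich probes would need a leaf share of 65.6%, but leaf-rich probes reached a median of 2.61% of their necrotic leaf level there. That leaf level is from 12 weeks of cold, since leaves after 6 weeks were not analysed here. Selection on the wild-type line as the whole cause would give a rise with classes from the necrotic line, but those 694 shoot-rich probes had a median of −1.32 (374 called at least 2-fold lower, 112 higher), and the 604 classed so in both lines −1.50. A scaling that acts alike on all probes of one abundance is argued against by 4147 equally abundant probes that were not tissue-rich, from which the shoot-rich median differed by −1.46. Quantile normalization gave −1.23, or 79.98% of the fall, at the edge of the bound set beforehand, so scaling as a part of the size cannot be told apart. The make-up and development of the shoot samples of the 2 lines stay open and untested, since a test would need probes with known marker genes.

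Across the cold tissues, 50 probes were well above background in the necrotic line and not in the wild-type line in both leaf and shoot, where 5.21 would be expected of independent lists, and 12 showed the opposite pattern, against 0.948 expected. Both expectations count all tested probes, among them 26795 well above background on all 10 arrays that could enter neither list, so they are too low. Over the 62 probes the brighter line lay a median of 2.52 on the log2 scale above the lowest level well above background. This was past the bound set beforehand against signals close to the detection limit. That level is the lowest among all probes detected on an array, and a counted probe lies at or above it by construction. The distance therefore cannot exclude such signals. A fixed difference between the lines in sequence or gene content may account for such probes, and it would leave most of the 50 detected in the necrotic leaf at 23 °C, but 21 of them were (42%, exact 95% interval 28.2% to 56.8%), and none of the 12, but 2 were (16.7%, 2.09% to 48.4%). Another 392 probes were detected in the necrotic but not the wild-type leaf and did not show that pattern in shoot. Of these, 129 were detected in the necrotic leaf at 23 °C (32.9%, 28.3% to 37.8%). These intervals treat probes as independent, which they are not, and all rest on the same 2 arrays at 23 °C. They do not measure variation among plants. The lowest level well above background was higher at 23 °C (−7.17 against −8.16), which lowers the 42%. Of the 39 probes whose cold leaf level lay above the level at 23 °C, 20 were detected (51.3%). A fixed difference in a gene that cold induces would be missed at 23 °C, so it cannot be told apart from a response to cold in the necrotic line.

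Probes whose names differ only by a leading r (1887 pairs with both tested) had differences that correlated across pairs at r = 0.60 in leaf, 0.69 in shoot and 0.60 for temperature. Where both were called at least 2-fold, 89 of 91 pairs had the same direction in leaf, 229 of 233 in shoot and 263 of 285 for temperature, while only 1 probe of the pair was called in 192, 271 and 499 pairs. For 259 pairs of names that differ by p or m, r was 0.27, 0.42 and 0.30. The sources used here do not say what these letters stand for. Among 39 families of probe names (156 Fisher's exact tests, two-sided, Benjamini-Hochberg adjusted; probes are not independent), the 1270 probes with names in MUG followed by a number stood out in the necrotic shoot. Of these 24.3% were at least 2-fold lower against 9.70% of other probes (adjusted p = 5.39e-47), and 2.52% were higher against 11.6%. In leaf they were below the others in both directions, with 3.62% higher against 7.08% and 0.945% lower against 3.44%. These probes overlap with the shoot-rich class, which holds 12.0% of them against 2.77% of other probes, and their median wild-type leaf minus shoot difference of −1.35 was the lowest of the 39 families. Outside that class 16.5% of them were at least 2-fold lower against 8.15% of others. Of the 156 tests 45 had an adjusted p under 0.05. Families with more probes at least 2-fold higher in the necrotic shoot than the others included MUGEST (15.2% against 10.4%, adjusted p = 1.17e-23), whr (24.0% against 11.04%, 4.19e-18), whkv (23.9% against 11.2%, 1.81e-05) and the names with a gi number (23.1% against 11.2%, 0.000226). What the name families stand for is not given in the sources used here.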
